A study of Mus musculus with 30 samples.

How the data were processed

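The series holds 30 mouse samples: 24 bulk RNA-seq libraries from eWAT and iWAT of 12 animals (6 WT and 6 SRF-AKO), 4 single-nucleus RNA-seq libraries and 2 SRF ChIP-seq libraries of differentiated 3T3-L1 cells. Groups were taken from the sample labels. Tags in the file names show that the 2 depots of a replicate number came from the same animal. Bulk RNA was made into libraries after depletion of ribosomal RNA with a kit that does not mark strand, and nuclei were prepared from frozen tissue with a droplet 3′ method, per the labels' protocols.

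For bulk RNA-seq the deposited values are raw read counts per gene, made with featureCounts 2.0.3 over exons of a UCSC mm10 annotation without strand, per the file headers. Reads of a gene and an antisense or overlapping gene could not be told apart, and near-identical copies share reads. For ChIP-seq the deposited values are raw read counts over one merged peak list, made with featureCounts 2.0.3 on BAM files without duplicates, per the file headers. In both, the option for paired reads was set without the one that counts pairs, so reads were counted. For nuclei the deposited values are UMI counts per gene and barcode. Tools named in the submitters' processing notes are fastp, Bowtie2, SAMtools, MACS2, featureCounts, STAR and Cell Ranger 7.1.0, with genome build mm10. No genome sequence was used here. Gene positions are those in the count files, and 144 genes on several chromosomes or strands carry more than one.

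Bulk libraries held 28854452 to 42490065 counted reads. The ribosomal precursor gene Rn45s took 4.47% to 6.57% of them, and mitochondrial genes were not among the 24421 genes of the files. No 2 replicates of a group agreed within sampling noise (chi-square per degree of freedom 9.98 to 163 over 60 pairs). Each depot was fitted alone with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, robust quasi-likelihood fit and test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Log2 changes are SRF-AKO minus WT, and levels are CPM, read counts scaled to TMM library sizes. The interaction was fitted over all 24 libraries. Of 25 gene lists written before the data were examined, those with enough tested members (23 in eWAT, 22 in iWAT, 23 for the interaction) were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with the estimated correlation, adjusted over the lists of a comparison. The epididymal and erythroid lists had too few tested members, as did the mammary list in iWAT. With the estimated correlation only the eWAT actin list passed (adjusted p = 0.0472), and the lowest value was 0.0889 in iWAT and 0.458 for the interaction. P-values of single genes measure the spread between animals. Camera p-values at the preset correlation and those of Fisher's exact test compare genes with genes, so they do not measure that spread.

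Named bulk genes were Srf, the called genes with the 8 largest log2 changes each way at a mean of at least 2 CPM and without predicted gene models, and up to 3 members per list with the smallest p. Genes named outside this rule were chosen after their values were seen, among them Acta1 in eWAT and Actb. For the interaction they were Srf and the genes with the 5 smallest p-values. Same-numbered WT and SRF-AKO libraries come from different animals. For the interaction, libraries of the 2 depots from the same animal are paired by design, and the correlation of their deviations from group means was 0.032 to 0.222 in WT and −0.007 to 0.203 in SRF-AKO. The main interaction fit did not use this pairing and treated these libraries as independent. A fit with the animal as a block was an alternative.

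Barcodes with under 500 genes or over 5% mitochondrial UMIs were removed (scanpy 1.11.5). Doublet scores came from Scrublet. Its automatic threshold marked 20.5%, 0%, 6.67% and 12.1% of the eWAT WT, eWAT SRF-AKO, iWAT WT and iWAT SRF-AKO barcodes. After this was seen, the top-scoring 0.8% of barcodes per 1000 loaded in a library were removed instead (8.86%, 5.82%, 6.53% and 10.45%), leaving 10007, 6775, 7583 and 11617 nuclei. All were clustered together (2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1). Clusters were named "-like" from markers written before the data were examined, with a scoring rule and thresholds set afterwards. UMIs were summed per library and class and divided by the class total, with exact Poisson or binomial 95% intervals that cover counting error only. Named genes had at least 50 UMIs over the 2 libraries of a depot, and ranked genes, ordered by the smaller of the depots' log2 ratios in 1 direction, at least 200. One gene that the rule for ranked genes takes is not reported here. A list's median was set among 10000 random lists matched on expression, for lists with at least 5 measured members.

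ChIP counts were divided by the sum over all 17704 regions. Regions with at least 50 counts per bp, summed over both libraries, are called dense, a limit set after the data were seen. Ratios carry exact binomial 95% intervals for counting error, and reads without molecular identifiers are not independent molecules. A gene counted as near a region when the region's centre lay within 5 kb of a transcription start.

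Alternatives were other normalization factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a replicate block, a fit of all libraries, each library left out, stricter nucleus filters, doublets kept, other clustering resolutions, other ChIP scalings and other distances. Leaving out libraries with muscle, epididymal or keratin transcripts, leaving out macrophage marker clusters for Eif4a2, scaling outside dense regions and a matched background were added after the data were seen. The steps were tested on simulated counts with 200 changed genes. At folds of 1.5, 2 and 4, edgeR recovered 44.8%, 77.6% and 86.4% in the eWAT design (15597 genes), 70.1%, 82.1% and 97.0% in iWAT (15086 genes) and 37.3%, 67.2% and 84.8% for the interaction (16016 genes), with 5.23%, 5.05% and 3.05% false calls. DESeq2 gave 16.8%, 14.5% and 11.6% false calls. Simulated ratio intervals covered the true value in 95.9% to 96.4% of cases. The simulated counts were independent draws, which counted reads of the same pair are not. This coverage therefore does not carry over to the ChIP intervals.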

Results

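Serum response factor (SRF), a transcription factor known for activating actin cytoskeleton and immediate-early genes, was studied in mouse fat in 30 samples of 3 kinds. Bulk RNA-seq compared mice that lack the Adipoq-CreERT2 transgene (WT) with mice that carry it (SRF-AKO), both homozygous for the floxed Srf allele and fed a high-fat diet. Adipoq-CreERT2 is a tamoxifen-inducible recombinase driven by the gene of the adipocyte hormone adiponectin. Epididymal (eWAT) and inguinal (iWAT) white adipose tissue was taken from the same 12 animals, 6 per genotype, which gave 24 libraries of 28854452 to 42490065 counted reads. Single-nucleus RNA-seq held 1 library per depot and genotype, with 7272 to 13058 barcodes and a median of 4490.5 to 6496 UMIs (unique molecules) per barcode. SRF ChIP-seq, which counts DNA fragments bound by SRF, was made from differentiated 3T3-L1 cells, a mouse preadipocyte line that can be turned into adipocytes in culture. It had 1 control library and 1 library of cells given 1 ng/mL TGFβ1, a cytokine of tissue fibrosis, with 5508331 and 5920047 reads counted in regions. Their labels give preadipocytes as the cell type, while the protocol describes differentiated cells.

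The first comparison asked what changed in eWAT of SRF-AKO mice. Srf itself (chromosome 17, 46546839 to 46556162, minus strand, mm10) had 60.4 ± 6.16 CPM (read counts scaled to library size, SD, n = 6) in WT and 44.4 ± 3.42 in SRF-AKO (log2 change −0.44, SE 0.0740). All 6 SRF-AKO libraries lay below all 6 WT libraries, but the adjusted p of edgeR's quasi-likelihood test was 0.0514. Srf passed with DESeq2 (adjusted p = 2.84e-05), voom (0.00591), no filter (0.0479), a fit of all 24 libraries (0.00272), and without WT replicate 6 (0.0248), SRF-AKO replicate 2 (0.0132) or SRF-AKO replicate 3 (0.0414). Whole tissue also holds Srf RNA of other cell types, and the deleted part of Srf is not given in the sources used here. Of 15742 genes tested, 5 were higher and 3 were lower in SRF-AKO. The 3 lower genes were Adgrl2, Kcnk3 and Col14a1. Adgrl2 is an adhesion G protein-coupled receptor on chromosome 3 (148815586 to 148954635, 71.5 ± 5.75 to 37.0 ± 2.25 CPM, log2 −0.95, adjusted p = 9.04e-06). Kcnk3 is a 2-pore potassium channel (93.6 ± 5.07 to 58.7 ± 8.32 CPM, log2 −0.67, adjusted p = 0.00593). Col14a1 is a fibril-associated collagen (188 ± 31.1 to 115 ± 13.2 CPM, log2 −0.71, adjusted p = 0.0435). The 5 higher genes were Mpdu1, Eif4a2, Kng2, Card14 and Plch2. Mpdu1 is needed for the use of mannose-phosphate-dolichol in glycosylation, on chromosome 11 (69656699 to 69662649, 61.9 ± 4.44 to 107.8 ± 11.8 CPM, log2 0.80, adjusted p = 0.000385). Eif4a2 is an RNA helicase of translation initiation (129 ± 6.64 to 181 ± 6.99 CPM, adjusted p = 0.000671) and Kng2 is a kininogen (0.902 ± 0.415 to 4.85 ± 0.791 CPM, adjusted p = 0.00236). Card14 rose from 1.73 ± 0.142 to 3.79 ± 0.991 CPM (adjusted p = 0.0331) and Plch2 from 4.64 ± 0.517 to 8.07 ± 1.41 CPM (adjusted p = 0.0435). When each library was left out, Col14a1 passed only without WT replicate 5 or SRF-AKO replicate 2 and Plch2 only without SRF-AKO replicate 2 or 3 (adjusted p up to 0.149 each). Card14 did not pass without any one of WT replicates 1 to 4 and 6 or SRF-AKO replicates 3 to 5 (up to 0.127). In each of these 8 genes all 6 SRF-AKO libraries lay beyond all 6 WT libraries, except Col14a1 with 5 of 6. Kng2 (22985852 to 23029101) and Eif4a2 (23107468 to 23114132) lie next to Adipoq (23146536 to 23157968) on chromosome 16, the gene whose sequences drive the transgene.

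Several eWAT libraries held transcripts of other tissues. The skeletal muscle list summed to 5690 CPM in SRF-AKO replicate 3 and to 23.3 to 31.2 CPM in the other 5 SRF-AKO libraries. The epididymal list summed to 458 CPM in WT replicate 5, 88.6 in SRF-AKO replicate 4 and 89.3 in SRF-AKO replicate 6, and to at most 0.240 in the other 9. Without the library with muscle transcripts, an alternative chosen after the data were seen, Acta1, the skeletal muscle α-actin (24.7 ± 4.82 to 3.23 ± 0.577 CPM, log2 −2.93, adjusted p = 1.6e-06), and Srf (log2 −0.48, adjusted p = 0.0414) were among 4 lower genes. Without the 4 libraries with muscle or epididymal transcripts, Mpdu1 was higher (adjusted p = 0.00873) and Adgrl2 (0.0029) and Acta1 (0.000377) were lower. Kng2 and Eif4a2 (0.0623 each), Kcnk3 (0.056), Col14a1 (0.0673), Card14 and Plch2 (0.272 each) did not pass. The number of calls also depended on the model and on single libraries. DESeq2 called 524 higher and 111 lower, limma voom with quality weights 23 and 27, and the fit of all 24 libraries about 3.2e+02 and 68. Leaving out SRF-AKO replicate 2 gave 272 higher and 81 lower, leaving out WT replicate 5 gave 9 and 5, and leaving out any one of WT replicates 1 to 4 or SRF-AKO replicates 4 and 5 gave 3 higher.

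Among gene lists fixed before the data were examined, genes of the actin cytoskeleton known as SRF targets were lower in eWAT as a group. Of 34 members, 28 had a negative log2 change (median −0.20), none passed over all genes tested, and 11 were lower when adjusted over the list alone. Examples were Acta2, the smooth muscle α-actin (169 ± 43.2 to 95.04 ± 15.0 CPM, adjusted p = 0.123), Actg1, cytoplasmic γ-actin (426 ± 40.1 to 284 ± 65.6 CPM, adjusted p = 0.126), and Vcl, the focal adhesion protein vinculin (322.1 ± 17.5 to 275 ± 8.86 CPM, adjusted p = 0.128). All 3 passed without SRF-AKO replicate 2 (0.0391, 0.00839 and 0.0455). The camera test, which compares a list with all other genes at a preset correlation of 0.01, gave an adjusted p of 1.4e-10. With an estimated correlation the adjusted p = 0.0472, which was 0.18 without the libraries with epididymal transcripts and 0.112 without those with muscle or epididymal transcripts. Extracellular matrix genes were also lower, with 24 of 25 negative, none past the threshold over all genes and 13 lower when adjusted over the list alone (camera adjusted p = 1.03e-16, adjusted p = 0.136 with an estimated correlation, and 0.0441 without the library with muscle transcripts). Among them were Postn, periostin (245 ± 39.9 to 139.8 ± 26.3 CPM, adjusted p = 0.0514, and 0.0338 without WT replicate 5), and Col1a1, a fibrillar collagen (2157 ± 309 to 1408 ± 255 CPM, adjusted p = 0.123). Both passed without SRF-AKO replicate 2 (0.0165 and 0.0131). All 20 macrophage genes were negative (camera adjusted p = 1.61e-07), as were all 15 immediate-early genes (camera adjusted p = 4.17e-05), each with an adjusted p = 0.6 with an estimated correlation. Lipogenesis (adjusted p = 0.0266), mesothelial (0.0157), mammary epithelial (0.0226) and skeletal muscle genes (0.0363) were higher in the camera test, and these had an adjusted p of 0.752 or 0.783 with an estimated correlation. Genes led by duct-like nuclei, at a median under 5 CPM, summed to 355.7, 187.0, 3791, 922.7, 2056 and 1094 CPM in SRF-AKO replicates 1 to 6, 867.9 in WT replicate 5 and 163.2 to 218.2 in the other 5 WT libraries. The skeletal muscle list was higher with the library that held muscle transcripts, and lower without it (camera adjusted p = 0.00143, median 0.136, mean −0.337), and lipogenesis genes did not pass without the libraries with epididymal transcripts (adjusted p = 0.185). Without the library with muscle transcripts, Acta1 (log2 −2.93) was the only called member of the skeletal muscle list. The other 15 of the 23 lists tested in eWAT did not pass, at adjusted p of 0.0574 to 0.835, among them thermogenic (0.39), oxidative phosphorylation (0.0601), hypoxia (0.49) and B and plasma cell genes (0.0574). The mechanical YAP list had a median of −0.085, a mean of 0.137 and a test direction of lower. The dendritic, mast cell and neutrophil list had 0.007, −0.018 and higher.

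In iWAT, Srf was lower (60.1 ± 4.84 to 42.6 ± 3.44 CPM, log2 −0.50, SE 0.0617, adjusted p = 0.00113, 6 of 6 libraries below all WT). Of 15202 genes tested, 40 were higher and 52 were lower. Actin genes were among the lower genes with the largest changes. Acta1 fell from 24.2 ± 4.39 to 2.26 ± 0.922 CPM (log2 −3.41, adjusted p = 5.17e-06), Acta2 from 176 ± 23.7 to 96.9 ± 17.8 CPM (log2 −0.86, adjusted p = 0.00468) and Actg1 from 311 ± 38.9 to 194 ± 19.0 CPM (log2 −0.68, adjusted p = 0.00151). Adgrl2 fell from 90.7 ± 5.55 to 42.3 ± 2.36 CPM (adjusted p = 3.23e-09). Ldb3, a protein of the muscle Z-disc (log2 −0.87), Rtn2, a reticulon (−0.81), Rap1gap2 (−0.73) and Nrarp, a Notch target (−0.65), completed the 8 largest decreases among called genes with a mean of at least 2 CPM. The largest increase was that of Kng2 (0.279 ± 0.0868 to 5.12 ± 0.476 CPM, log2 4.18, adjusted p = 3.23e-09). The other 7 of the 8 largest increases among called genes at that level were those of Cma1, a chymase (7.58 ± 1.54 to 15.2 ± 2.97 CPM, log2 1.01), Cpa3, a carboxypeptidase (log2 0.98), Lgi2 (0.96), Mcpt4, another chymase (0.92), Tpsb2, a tryptase (0.91), Car12, a carbonic anhydrase (0.89), and Sfrp2, a secreted Wnt modulator (0.89). Cma1, Cpa3, Mcpt4 and Tpsb2 were among the leading genes of the mast-like nuclei (cluster 30). These nuclei made up 0.831% (0.639 to 1.062) of the iWAT WT library and 0.955% (0.787 to 1.15) of the iWAT SRF-AKO library. The mixed list of dendritic, mast cell and neutrophil genes, which holds Cpa3 and Mcpt4, did not pass (camera adjusted p = 0.0897, and 0.0268 without libraries with keratin transcripts, median −0.02, mean 0.112, test direction higher). In each of these named genes all 6 SRF-AKO libraries lay beyond all 6 WT libraries, except Nrarp with 5 of 6. When each library was left out, Nrarp passed only without WT replicate 4 or SRF-AKO replicate 5 (adjusted p up to 0.106). Cpa3 did not pass without any one of WT replicates 2, 3, 4 and 6 or SRF-AKO replicates 2, 4, 5 and 6 (up to 0.0889). The same held for Car12 without any one of WT replicates 2, 4, 5 and 6 or SRF-AKO replicates 3 to 6 (up to 0.0889) and for Sfrp2 without any one of WT replicates 2, 5 and 6 or SRF-AKO replicates 5 and 6 (up to 0.0748). In the fit of all 24 libraries, Acta1 (0.605), Ldb3 (0.884), Sfrp2 (0.227) and Car12 (0.167) did not pass. That fit takes the spread from both depots and holds the eWAT SRF-AKO library with muscle transcripts. The eWAT SRF-AKO levels were 441.2 ± 1073 CPM for Acta1 and 39.72 ± 81.98 CPM for Ldb3.

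**Figure D1:**
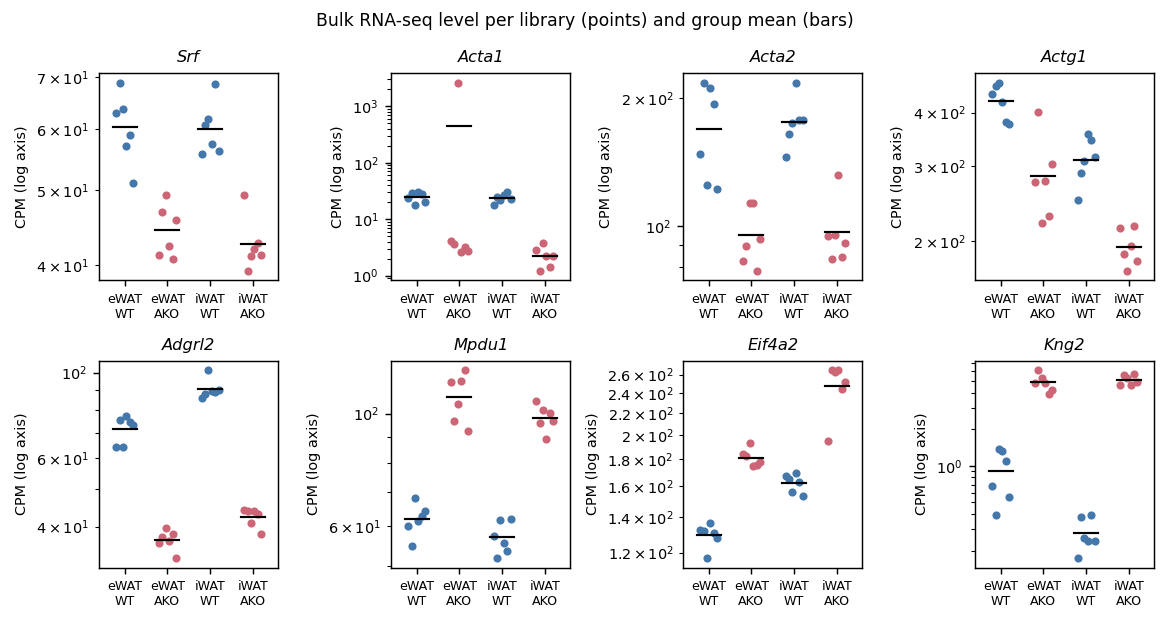
Bulk RNA-seq levels of 8 genes in CPM on a log axis, with 1 point per library (6 per group) and a bar at each group mean. Srf, Acta2, Actg1 and Adgrl2 lie lower in SRF-AKO in both depots, Acta1 is lower except in 1 eWAT library with muscle transcripts, and Mpdu1, Eif4a2 and Kng2 lie higher.

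The actin cytoskeleton list was lower in iWAT, with 28 of 34 members negative, 7 past the threshold over all genes and 11 lower and 1 higher when adjusted over the list alone. Called members included Flna, the actin crosslinker filamin A (1517 ± 109 to 985 ± 71.6 CPM, adjusted p = 5.64e-05), Actb, cytoplasmic β-actin (3653 ± 302 to 2608 ± 255 CPM, adjusted p = 0.00468), and Tgfb1i1, a focal adhesion protein (46.1 ± 3.25 to 34.7 ± 1.90 CPM, adjusted p = 0.00201). The camera adjusted p was 5.64e-14, with an adjusted p = 0.0889 with an estimated correlation. Endothelial genes were lower as a group (camera adjusted p = 7e-06, adjusted p = 0.0889 with an estimated correlation), with Kdr, a VEGF receptor (341 ± 19.6 to 280 ± 13.7 CPM, adjusted p = 0.01), and Cdh5, VE-cadherin (662 ± 55.3 to 534 ± 36.1 CPM, adjusted p = 0.0272), past the threshold. Cdh5 did not pass without any one of WT replicates 3, 5 and 6 or SRF-AKO replicates 2, 3, 4 and 6 (up to 0.0809). In the fit of all 24 libraries Actb (0.168), Kdr (0.427) and Cdh5 (0.321) did not pass. All 15 T and NK cell genes were negative, none past the threshold over all genes and 8 when adjusted over the list alone (camera adjusted p = 7.2e-09, adjusted p = 0.11 with an estimated correlation), for example Cd8b1 at 1.44 ± 0.715 and 0.469 ± 0.216 CPM. Macrophage genes (17 of 20 positive, camera adjusted p = 2.76e-06) and fibroblast and progenitor genes (12 of 17 positive, camera adjusted p = 0.00116) were higher, with adjusted p = 0.258 and adjusted p = 0.0889 with an estimated correlation. Among the latter were Dcn, decorin (491 ± 44.4 to 581 ± 38.1 CPM, adjusted p = 0.0948), and Ly6a (75.0 ± 7.47 to 88.7 ± 4.30 CPM, adjusted p = 0.0787). Focal adhesion (adjusted p = 0.00765) and oxidative phosphorylation genes (0.022) were lower, and TGFβ response (0.0395) and mesothelial genes (0.022) higher, in the camera test, with adjusted p of 0.186, 0.582, 0.11 and 0.186 with an estimated correlation. The skeletal muscle list was lower, with Acta1 its only called member, at a median of 0.003 and a mean of −0.33 (camera adjusted p = 0.00285, adjusted p = 0.0889 with an estimated correlation). The other 12 of 22 lists did not pass, at adjusted p of 0.0604 to 0.83, among them extracellular matrix (0.0897), inflammatory cytokine (0.0604) and immediate-early genes (0.163). SRF-AKO replicates 3 and 4 held keratin transcripts (mammary epithelial list 36.1 and 48.5 CPM, against at most 2.51 in the other 10). Without them 46 genes were higher and 30 lower, and TGFβ response (adjusted p = 0.055) and mesothelial genes (0.124) did not pass. DESeq2 called 202 higher and 185 lower, voom 80 and 102, and the fit of all 24 libraries 28 and 20. Without SRF-AKO replicate 1 there were 124 higher and 115 lower, without WT replicate 2 there were 25 and 33, and without SRF-AKO replicate 6 there were 25 and 28. The lower genes numbered 27 without WT replicate 5 and 33 without SRF-AKO replicate 4.

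Whether the depots differed in their response was tested as an interaction of genotype and depot. The main fit did not pair the depots of an animal. Thbs2, a matricellular protein of the thrombospondin family, was the 1 gene called among 16119. It was at 154.5 ± 9.28 CPM in WT and 120.4 ± 16.2 in SRF-AKO in eWAT (adjusted p = 0.128 in eWAT alone), and at 140.2 ± 21.6 and 208.1 ± 13.5 CPM in iWAT (adjusted p = 0.0133 in iWAT alone, and 0.0558 without keratin libraries). The log2 changes differed by −0.93 (eWAT minus iWAT, SE 0.131, adjusted p = 0.00361), which did not pass without the libraries with muscle, epididymal or keratin transcripts (−0.94, adjusted p = 0.189). SRF-AKO replicates 1 and 5 of eWAT, with duct-like genes at 355.7 and 2056 CPM, stayed in this alternative. Srf did not differ in its change between depots at this depth (difference 0.05, SE 0.0979, adjusted p = 0.905). Kng2 (−1.75), Thbs1 (−1.29), Dnah6 (4.27) and Ttc16 (4.07) had the next smallest p-values, each with an adjusted p of 0.111. In eWAT SRF-AKO replicates 1 to 6, Dnah6 was at 4.22, 1.029, 51.99, 7.447, 25 and 11.05 CPM and Ttc16 at 1.191, 0.3087, 10.15, 1.418, 3.553 and 1.451 CPM, and the duct-like genes were highest in replicates 3 and 5 as well. Macrophage genes (camera adjusted p = 5.77e-13), extracellular matrix genes (1.76e-08) and fibroblast and progenitor genes (0.0378) were lower in eWAT relative to iWAT, with an adjusted p of 0.458 each with an estimated correlation. T and NK cell (1.66e-05), oxidative phosphorylation (0.000346) and skeletal muscle genes (0.00551) were higher, with adjusted p of 0.541, 0.664 and 0.664 with an estimated correlation. With the animal as a block the fibroblast list (adjusted p = 0.0658) and the skeletal muscle list (0.207) did not pass. Without the libraries with muscle, epididymal or keratin transcripts the latter was at 0.826. The other 17 lists did not pass, the actin list among them (adjusted p = 0.336). Median, mean and test direction differed in sign for the actin (−0.033, 0.004, lower), mechanical YAP (0.018, 0.123, lower), hypoxia (−0.023, 0.007, higher), mesothelial (0.004, −0.505, lower) and nerve lists (−0.015, 0.12, lower). DESeq2 called 61 genes in 1 direction and 34 in the other, and edgeR called 0 without the libraries with muscle, epididymal or keratin transcripts (626 and 684 genes at an unadjusted p under 0.05). As for overlap, 3 genes were higher in both depots (Eif4a2, Kng2 and Mpdu1; 0.0133 for independent lists, Fisher's exact test, two-sided, p = 1.75e-07) and 2 were lower in both (Adgrl2 and Kcnk3; 0.0104, p = 3.52e-05), among 15012 genes tested in both. In iWAT, Kcnk3 did not pass without any one of WT replicates 5 and 6 or SRF-AKO replicates 2, 4 and 6 (adjusted p up to 0.0722), or in the fit of all 24 libraries (0.0674). The depots came from the same animals, so chance differences between animals are shared. Without the library with muscle transcripts, 4 genes were lower in both, Acta1, Adgrl2, Kcnk3 and Srf, and DESeq2 calls gave 18 genes higher and 21 lower in both.

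The nuclei showed which cell classes each library held. With 1 library per group there is no replicate and no test, and intervals are exact 95% intervals for counting error only. In all, 35982 nuclei were kept and fell into 36 clusters. Adipocyte-like nuclei made up 5.94% (5.48 to 6.42) of the eWAT WT library and 9.39% (8.70 to 10.1) of the eWAT library labelled SRF-AKO, and 16.4% (15.6 to 17.3) and 11.6% (11.1 to 12.2) in iWAT. Shares of clusters with macrophage markers were not summed over the class, since the leading genes of cluster 17 among them held 4 haemoglobin genes (481, 194, 48 and 115 nuclei in eWAT WT, eWAT SRF-AKO, iWAT WT and iWAT SRF-AKO). In the same order, the other 6 held 2.60%, 4.19%, 6.99% and 8.73% (cluster 3), 6.63%, 8.46%, 1.29% and 1.80% (cluster 6), 0.59%, 0.83%, 8.11% and 6.40% (cluster 7), 3.31%, 6.33%, 2.23% and 3.06% (cluster 12), 1.63%, 2.30%, 3.48% and 3.64% (cluster 14) and 1.68%, 2.11%, 1.15% and 1.22% (cluster 22). Endothelial-like nuclei made up 10.9% and 6.70% in eWAT and 15.0% and 14.4% in iWAT, and T or NK-like nuclei 15.5% and 12.5% in eWAT and 3.24% and 4.48% in iWAT (2.11% and 3.84% in iWAT at a Leiden resolution of 0.5). Fibroblast or progenitor-like nuclei made up 8.53% and 10.7% in eWAT and 31.6% and 33.5% in iWAT. Unnamed clusters held 11.1%, 2.01%, 3.26% and 1.70% of the eWAT WT, eWAT SRF-AKO, iWAT WT and iWAT SRF-AKO libraries, and 11.1% to 21.4%, 2.01% to 7.49%, 3.26% to 6.91% and 1.70% to 5.51% over all clustering and filter settings. They include 869 nuclei in clusters 19 and 34 that all came from the eWAT WT library and were led by Pkhd1, a gene of ciliated duct epithelium, and by genes of motile cilia. Nuclei had been sorted with a DNA dye to remove debris and multiplets, and the sort, the depth of a library and what was dissected with the fat can set these shares.

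Within adipocyte-like nuclei, Srf UMIs went against the label. Srf had 3.76 CPM of the class sum (2.79 to 4.96, 50 UMIs) in eWAT WT and 20.5 CPM (17.7 to 23.7, 184 UMIs) in the library labelled SRF-AKO, a ratio of 5.46 (3.98 to 7.63), and in iWAT 4.46 and 9.01 CPM, a ratio of 2.02 (1.52 to 2.71). A 3′ tag outside the deleted part checks nothing, and the deleted part is not given in the sources used here. Actin genes were lower in both libraries labelled SRF-AKO. Acta1 had 165 UMIs against 5 in eWAT (ratio 0.0450, 0.0144 to 0.107) and 62 against 1 in iWAT (0.0219, 0.000546 to 0.127). Acta1 was also lower outside this class, with 38 against 0 UMIs in eWAT and 51 against 0 in iWAT in endothelial-like nuclei, where its iWAT WT level (8.21 CPM) lay above that of adipocyte-like nuclei (3.37 CPM). The adipocyte gene Adipoq had 465 CPM in endothelial-like nuclei of eWAT WT against 703 CPM in adipocyte-like nuclei, at median depths of 4635.5 and 21519 UMIs. The ratios were 0.282 and 0.388 for Acta2, 0.340 and 0.545 for Actg1, 0.528 and 0.628 for Actb, and 0.509 and 0.368 for Flna, in eWAT and iWAT. Of the actin list, 26 of 29 measured members were lower in eWAT (median log2 −0.52, below all of 10000 random lists matched on expression), and 20 of 28 in iWAT (median −0.06, percentile 18.4). Adrb3, the β3-adrenergic receptor of adipocytes, was higher (ratio 5.26 in eWAT and 1.82 in iWAT), as was Mpdu1 (1.89 and 1.85). In bulk eWAT without the library with muscle transcripts, Adrb3 did not pass in edgeR's test (adjusted p = 0.781). It was at 51.98 ± 16.45 CPM in WT and 62.79 ± 17.92 in SRF-AKO there (log2 0.27). Of the 20 adipocyte identity genes, which include Adrb3, 11 were lower in eWAT adipocyte-like nuclei. Adgrl2 was lower (0.648 and 0.656). Itgad, Gnal, Mir142hg, 4931431B13Rik, Lmcd1, Prune2 and Srf were among the 8 genes with the highest ratios in both depots. Oxidative phosphorylation genes had a median log2 ratio of −0.33 in eWAT (20 of 22 lower, percentile 0) and −0.07 in iWAT (percentile 10.2). Mitochondrial UMIs of these nuclei made up 0.594% and 0.101% in eWAT WT and SRF-AKO and 0.06% and 0.07% in iWAT. The medians were, for thermogenic genes −0.38 (percentile 0.2) and −0.12, adipocyte identity genes −0.20 (percentile 1.02) and 0.10 (percentile 99.5), lipogenesis genes 0.06 and −0.10, and extracellular matrix genes −0.20 (percentile 0.1) and 0.26 (percentile 100). Genes of other cell types shifted in these nuclei too, with medians of −1.14 and 0.60 for endothelial genes, −0.29 and 1.10 for macrophage genes, −0.13 (percentile 4.07) and 0.56 (14 of 17 higher, percentile 100) for fibroblast and progenitor genes, and −0.42 (11 of 14 lower, percentile 0.03) and 0.08 for smooth muscle and pericyte genes in eWAT and iWAT. In the same order, medians were 0.83 (10 of 10 higher, percentile 100) and 0.58 (7 of 10 higher) for T and NK cell genes. They were 0.52 (9 of 11 higher, percentile 99.7) and 0.24 (3 of 5 higher) for B and plasma cell genes, and −2.82 (4 of 5 lower, percentile 0) and 0.60 (4 of 5 higher) for erythroid genes. Igkc, a plasma cell gene, and Pkhd1 were among the 8 genes with the lowest ratios in both depots, with Cttnbp2, Acta2, Specc1, Spef2, Lpar3 and Flna. Most adipocyte-like nuclei of eWAT were in cluster 11 and most of iWAT in cluster 5, in both genotypes. With doublets kept the Actg1 iWAT adipocyte-like log2 ratio was −0.26 against −0.87 and the Specc1 iWAT adipocyte-like log2 ratio −0.25 against −1.19. Their median depth was 21519 and 13335 UMIs in eWAT and 13539 and 9231.5 in iWAT.

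**Figure D2:**
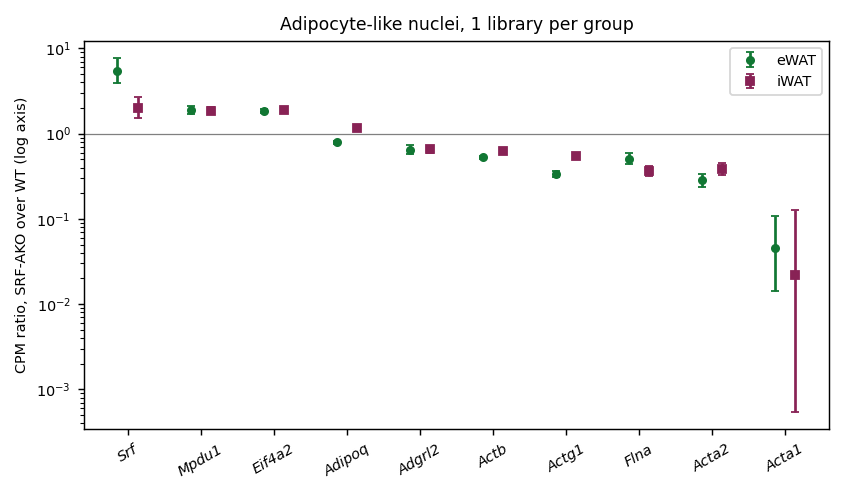
Ratio of CPM in the adipocyte-like nuclei of the library labelled SRF-AKO over that of WT, on a log axis, for 10 genes in eWAT (circles) and iWAT (squares). Bars are 95% intervals for counting error, and the line marks a ratio of 1. Srf, Mpdu1 and Eif4a2 lie above 1 and the actin genes and Adgrl2 below 1 in both depots.

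The ChIP-seq libraries addressed where SRF bound and whether TGFβ1 altered it. SRF regions lay near the start of Srf itself (chromosome 17, 46556131 to 46556449, mm10), with 210 reads in control and 309 with TGFβ1, of Actb (chromosome 5, 142906578 to 142906977), with 865 and 920 reads, and of the immediate-early genes Egr1 (chromosome 18, 34860684 to 34861292), with 541 and 682 reads, and Ier2 (chromosome 8, 84663769 to 84664314), with 855 and 1122 reads. Relative to all reads in regions, the ratio of TGFβ1 over control was 1.37 (95% interval for counting error 1.15 to 1.64) for Srf, 0.990 (0.901 to 1.09) for Actb, 1.17 (1.05 to 1.32) for Egr1, 1.22 (1.12 to 1.34) for Ier2, 2.12 (1.304 to 3.54) for a region inside Acta2 (chromosome 19, 34254153 to 34254466, 25 and 57 reads) and 1.98 (1.43 to 2.76) for Actg1 (chromosome 11, 120348399 to 120348652, 57 and 121 reads). There was 1 library per condition, so these values compare 2 libraries and have no replicate check, and no input library was used here. Where both reads of a pair were counted, the intervals are narrower than intervals for fragments would be. Of 17704 regions, 43 very dense ones held 83.5% of the reads in control and 80.6% with TGFβ1, 34 of them at the start of chromosome 9 (3000086 to 3038177). Among 10774 regions with at least 50 reads, 1128 had a ratio of 2 or more and 95 a ratio as far below 1. With scaling by the median ratio these were 546 and 279, and with scaling to the reads outside the dense regions, chosen after the data were seen, 595 and 250. The median log2 ratio of these regions was 0.27, 0.01 and 0.04 on the 3 scales. On the last scale the ratios were 0.997 (0.889 to 1.12) for Egr1, 1.04 (0.948 to 1.14) for Ier2, 1.16 (0.973 to 1.39) for Srf, 0.841 (0.765 to 0.924) for Actb, 1.80 (1.11 to 3.01) for Acta2 and 1.68 (1.22 to 2.34) for Actg1.

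**Figure D3:**
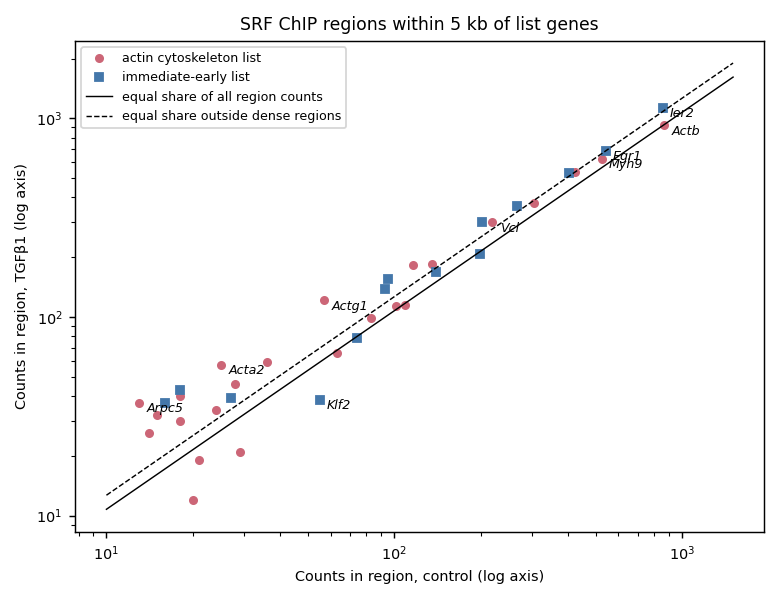
Reads per SRF region in control (x) and with TGFβ1 (y), both on log axes, for regions within 5 kb of the start of genes of the actin cytoskeleton list (circles) and the immediate-early list (squares). The solid line marks equal shares of all region reads and the dashed line equal shares of reads outside the dense regions; Actb lies near the solid line, and Acta2 and Actg1 lie above both.

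Finally, genes called in SRF-AKO mice were compared with the SRF regions of the cell line. Of the 52 genes lower in iWAT, 16 (30.8%) had a region within 5 kb of a start site, against 42.5% of tested genes not called (Fisher's exact test, two-sided, p = 0.0929). Of the 40 genes higher in iWAT, 10 (25.0%) did, which was fewer than among the other genes (odds ratio 0.450, exact p = 0.0252). In eWAT these were 1 of 5 higher genes (exact p = 0.411) and 1 of 3 lower genes (exact p = 1.0). Lower iWAT genes with a region within 5 kb included Srf, Actb, Actg1, Acta2, Flna and Ldb3, and higher ones Mpdu1 and Thbs2, of which Ldb3, Mpdu1 and Thbs2 were picked out after their values were seen. With 1 kb the lower iWAT genes were near a region less often than other genes (exact p = 0.0189), and with 50 kb the higher ones did not pass (exact p = 0.0554).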

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

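The tests of Eif4a2 in other cell classes, of the position of called genes near Adipoq, of duct genes per library and of background RNA were chosen only after the results were seen. The splits of samples, the share of duct genes among calls and the test for swapped labels were fixed before their results.

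Kng2 and Eif4a2 were higher in SRF-AKO and lie next to Adipoq. The neighbouring Rfc4 (3.22 ± 0.773 and 4.92 ± 0.876 CPM in iWAT) did not pass (adjusted p = 0.197 in eWAT and 0.128 in iWAT), and its 3′ end overlaps Eif4a2 in counts without strand. A response within adipocytes alone is argued against by the Eif4a2 ratio, which lay above 1 beyond counting error in all 15 other class and depot combinations with at least 200 Eif4a2 UMIs (1.56 to 2.03), and in all 13 without the clusters with macrophage markers, which include cluster 17 with haemoglobin genes and were left out after the data were seen. An example is 1.62 in iWAT fibroblast or progenitor-like nuclei, where Adipoq was at 11.1 CPM against 562 in adipocyte-like nuclei. In eWAT WT, Adipoq in endothelial-like nuclei lay closer to its adipocyte-like level, as given above. The combinations share 1 library per depot and genotype, so they are not independent checks. Below 200 UMIs, Eif4a2 ratios were 1.29 (0.762 to 2.23) in iWAT lymphatic endothelial-like, 1.31 (0.390 to 3.96) and 2.18 (1.24 to 4.06) in eWAT and iWAT mast-like and 1.82 (1.33 to 2.51) in iWAT dendritic-like nuclei. Extra copies of these genes on the transgene and a strain variant linked to it both stay open. Of the 40 genes called higher in iWAT, 2 lie within 150 kb of Adipoq, against 5 of 15162 others (Fisher's exact test, two-sided, p = 0.000141), but these 2 prompted the explanation, so the count tests nothing, as does an earlier one on neighbours of Adipoq (5 of 6 genes within 150 kb over a ratio of 1.3 against 0 of 22 farther off, exact p = 6.11e-05).

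Epithelial transcripts were high in several eWAT SRF-AKO libraries. Of 524 genes that DESeq2 called higher in eWAT, 188 (35.9%) were led by the duct-like nuclei of clusters 19 and 34, against 162 of 17429 others (0.93%), a ratio of 38.6, which restates the pattern and would hold for ducts dissected with some fat pads and for a response of the tissue alike. Duct-like genes under a median of 5 CPM summed to 355.7, 187.0, 3791, 922.7, 2056 and 1094 CPM in SRF-AKO replicates 1 to 6, 163.2 to 218.2 in 5 WT libraries and 867.9 in WT replicate 5. Of the SRF-AKO libraries, 2 lay below the highest WT library, which held epididymal transcripts, and 1 lay within the range of the other 5 WT libraries, which excludes neither. All 869 nuclei of clusters 19 and 34 came from the eWAT WT library and none from SRF-AKO, so duct-like nuclei were present without Srf loss, but with 1 nucleus library per genotype a response of eWAT to Srf loss in the bulk libraries is not excluded and stays open beside dissected ducts.

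Srf UMIs were higher in adipocyte-like nuclei of the libraries labelled SRF-AKO, against the label. Background RNA is argued against in eWAT by the larger other classes. Their highest Srf level in the eWAT SRF-AKO library was 10.6 CPM, below the lower bound of 17.7 CPM in adipocyte-like nuclei. Mural-like, dendritic-like and mast-like nuclei (864880, 320239 and 33165 UMIs in that library) and unnamed nuclei were not compared. Swapped labels are argued against by the bulk iWAT calls, of which 59 of 74 (79.7%) in eWAT and 58 of 74 (78.4%) in iWAT had the bulk sign in adipocyte-like nuclei. Tags outside the deleted part or a raised level of an altered transcript could account for the UMIs and were not tested. The ratios of Acta1, Acta2, Actg1, Actb and Flna, which do not depend on the Srf tags, lay below 1 in adipocyte-like nuclei of both depots. Of the whole actin list, 26 of 29 measured members were lower in eWAT and 20 of 28 in iWAT. The iWAT median lay within the range of random lists (percentile 18.4).

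Among 137 groups of 6 libraries examined, 12 (8.8%) held a library far from the others, and chance gives about 1 in 20. In iWAT SRF-AKO, Srf was 49.24 CPM in replicate 1 (others 39.33 to 42.68), Eif4a2 194.6 in replicate 1 (others 244.3 to 265.2), Acta2 131.7 in replicate 4, Ldb3 2.268 in replicate 5, Cd14 10.29 in replicate 4, and total reads 29710468 in replicate 2. In iWAT WT, replicate 3 had Adgrl2 at 101.6 CPM, Rap1gap2 at 86.93 and Thbs2 at 97.39 (others 139.2 to 157.9). In eWAT, WT replicate 5 had the epididymal list at 457.7 CPM and the mammary list at 82.58, and SRF-AKO replicate 3 the skeletal muscle list at 5690.

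The genotype effect on Thbs2 differed between depots by −0.929 in log2. Differences in nucleus shares between genotypes went opposite ways in the depots and were not tested: SRF-AKO minus WT was 3.45 percentage points in eWAT and −4.78 in iWAT for adipocyte-like, −1.27 and 0.94 for mural-like, and −2.95 and 1.23 for T or NK-like nuclei.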

How the results depend on the processing

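Leaving out libraries with muscle, epididymal or keratin transcripts, scaling outside the dense ChIP regions and the matched background were chosen after the data were seen. Of 1203 alternative values for 65 named bulk genes, 1034 kept their direction and side of the threshold, 103 lost and 59 gained a call, and 7 reversed. Of alternatives to the results that answer a comparison on their own, 92 stayed the same, 52 moved, 2 became stronger, 1 became weaker and 1 reversed. Of values without a test that answer no comparison on their own, 69 moved. Causes were not tested unless named.

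Genes higher and lower in eWAT (5 and 3) numbered 524 and 111 with DESeq2, 23 and 27 with voom, 3.2e+02 (rounded) and 68 in the fit of all 24 libraries, and 1 higher without the libraries with muscle or epididymal transcripts. Leaving out each library gave 3 to 272 higher and 2 to 81 lower. In iWAT (40 and 52) they were 202 and 185 with DESeq2, 80 and 102 with voom, 20 lower in the fit of all 24 and 30 lower without keratin libraries, and 25 to 124 higher and 27 to 115 lower when each library was left out. The interaction gave 95 genes with DESeq2 and 0 without the libraries with muscle, epididymal or keratin transcripts, which keeps eWAT SRF-AKO replicates 1 and 5 with duct-like transcripts. Lists past the threshold fell to 1 in eWAT and 0 in iWAT and the interaction with an estimated correlation. Genes shared by the depots were 18 higher and 21 lower with DESeq2, and 4 lower without the muscle library.

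Same-numbered WT and SRF-AKO libraries share only a number (r −0.246 to 0.274 in eWAT, −0.166 to 0.184 in iWAT, with 2 and 1 of 6 correlating best with their own number). With the replicate block eWAT gave 22 higher and 11 lower and iWAT 31 and 48. In eWAT the lipogenesis and skeletal muscle lists were then at an adjusted p of 0.123, the actin list at 0.263 with an estimated correlation, and B and plasma cell genes at 0.038. Card14 was lost (0.061) and Postn gained (0.0263), and in iWAT Nrarp (0.109), Cpa3 (0.1), Car12 (0.1) and Sfrp2 (0.0534) were lost. In iWAT inflammatory cytokine genes were at 0.026. With the animal as block the interaction kept 1 gene.

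The eWAT change of Acta1 (4.15 in log2) reversed to −2.215 with voom, −2.266 with the block, −2.93 without the library with muscle transcripts (SRF-AKO replicate 3; −2.93 to 4.415 over libraries left out) and −2.738 without muscle or epididymal libraries. The interaction of Srf was −0.026 with voom and −0.019 without muscle, epididymal or keratin libraries. The eWAT skeletal muscle list turned lower, at 0.00143 without the muscle library and 0.0203 without muscle or epididymal libraries. Without the muscle library B and plasma cell genes passed (0.00733). Other lists that passed without muscle, epididymal or keratin libraries were oxidative phosphorylation in eWAT (0.0154 and 0.00376), mechanical YAP genes in eWAT (0.0298), dendritic, mast and neutrophil (0.0268), inflammatory cytokine (0.0268) and smooth muscle genes (0.00279) in iWAT, and adipocyte identity in the interaction (0.0468). The list values in this paragraph are camera adjusted p at the preset correlation. With an estimated correlation only the eWAT actin list passed in the main fits.

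With at least 1000 genes per nucleus, adipocyte-like shares were 4.67% and 7.872% in eWAT WT and SRF-AKO and 11.049% in iWAT SRF-AKO. With doublets kept they were 18.031% and 13.482% in iWAT, and the Col14a1 eWAT adipocyte-like log2 ratio turned from −1.2094 to 0.1174. ChIP regions with a ratio of 2 or more, or as far below 1, were 546 and 279 with median scaling, 595 and 250 outside dense regions, and 2901 and 930 over all regions. For genes near regions, the eWAT higher genes reversed at 50 kb (exact p = 1.0), the iWAT higher genes were at 0.0554 at 50 kb, and the iWAT lower genes at 0.0189 at 1 kb and 0.0066 with the matched background. With 1 library per group, nuclei and ChIP ratios have no replicate check.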

Other observations

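The list test of SRF regions and the class values below were chosen after the data were seen. Among fixed gene lists, SRF regions of 3T3-L1 cells lay within 5 kb of 14 of 15 immediate-early genes (93.3%, against 40.8% of 16105 genes, Fisher's exact test, two-sided, adjusted p = 0.00075 over 23 lists) and of 24 of 34 actin cytoskeleton genes (70.6%, adjusted p = 0.00337). Of 10000 draws matched on expression in bulk fat, 2 and 120 reached as many. No member of the T and NK cell, endothelial or smooth muscle and pericyte lists was near a region (0 of 15, 0 of 15 and 0 of 14, adjusted p = 0.00337 each). The same held for B and plasma cell genes, for dendritic, mast cell and neutrophil genes (0 of 11 each) and for mesothelial genes (0 of 10). The genes compared with were those tested in bulk fat, and expression in 3T3-L1 cells was not measured. These counts therefore say nothing on SRF binding in other cell types.

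By cell class, Mpdu1 had a ratio of SRF-AKO over WT of 1.89 (1.70 to 2.10) and 1.85 (1.69 to 2.03) in adipocyte-like nuclei of eWAT and iWAT, and of 0.974 and 1.05 in fibroblast or progenitor-like and 1.04 and 1.09 in endothelial-like nuclei, with 1.44 (1.09 to 1.90) in mesothelial-like nuclei. Adgrl2 was highest in endothelial-like nuclei (437 and 482.6 CPM in WT) and its ratio was 0.575 and 0.602 there. Acta2 had ratios of 1.92 in eWAT and 0.974 in iWAT in mural-like nuclei, where its level was highest. With 1 library per group these values have no test.

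Random splits of the 12 libraries of a depot, or of the 12 animals, were refitted, 100 each with the real one included. As many genes were called in 1 of 100 splits in each depot and direction (real 5 and 3 in eWAT and 40 and 52 in iWAT, highest other 1 in each). Chance is therefore excluded for these counts at 5 in 100. For the interaction, as many were called in 2 of 100 (real 1, highest other 1). Splits of whole animals also put genotype effects common to both depots into the spread, so they cannot exclude chance for the interaction. A camera p as small for the actin list came in 3 of 100 splits in eWAT (real 1.21e-11, smallest other 1.07e-12) and 3 of 100 in iWAT (2.56e-15 and 1.9e-15). Chance was not excluded for the number of lists past the threshold, reached in 56 of 100 splits in eWAT (real 8, highest other 15), 9 in iWAT (10 and 11) and 56 for the interaction (6 and 13).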
